A study of Mus musculus with 27 samples.

How the data were processed

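The series deposited a table of read counts per gene and a table of relative transcript abundance (TPM) per gene for 27 libraries, and the counts were the starting point for every comparison. The 18 nucleoplasm and cytoplasm columns of the first table are read counts, per the file headers. The 9 chromatin columns of that table, deposited under headers with the abbreviation Chr, hold whole-number read counts of the same kind and were analysed as counts. The values of the second table are TPM, per the file headers, summed per gene by the authors. Per the submitters' processing notes, STAR, featureCounts and kallisto 0.43.0 were used with the mouse build mm10. The order of these steps, the counting options, the strand setting, the annotation release and the transcript set behind the TPM values are not given in the sources used here. The deposited gene length equals the distance from start to end in each of 37332 genes of the count table, so introns lie inside the counted region.

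Genes were matched by Ensembl identifier to the GENCODE M21 annotation, which gave a symbol to 35449 of the 37332 genes of the count table and to 53274 of the 53379 of the TPM table. The tables share 35509 genes. Of the count table's genes, 35533 have a biotype, and 68.0% of the matched ones have the same start and end in both annotations. Genes without a symbol stayed in the fit. Coordinates are those of the count table in mm10. Library totals ran from 10622897 to 24537526 counts. Where a gene lies inside a larger gene on the same strand, none of 802 inner genes had more counts than the outer one, against 170 of 583 (29.2%) on opposite strands. Reads in overlapping genes of one strand are therefore shared, and such genes are named as overlapping.

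Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 9 groups, which left 18226 of them. Libraries were scaled by TMM. A single quasi-likelihood fit of all 27 libraries with a mean per group shared the spread across groups, and the quasi-likelihood F-test was run for 13 contrasts. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast. A gene was called when the adjusted p was under 0.05 and the fitted log2 fold change was at least 1 in size. The SE given with a log2 fold change is its size divided by the square root of the F statistic. Levels are in CPM, the count over the TMM-scaled library size as edgeR gives it, as mean ± SD of 3 libraries. The levels are relative to the RNA of each fraction, so they give no amount per cell.

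The 13 contrasts are the 3 pairs of fractions in each of 3 cell types, the cytoplasm of mNPC against mESC and of mCtx against mNPC, and the same pairs of cell types for the difference of their chromatin-to-cytoplasm log2 fold changes. These contrasts, the gene lists, the alternatives of each processing choice and the rule for naming genes were fixed before the data were examined. The rule named the 8 called genes with the largest change in each direction for the chromatin-to-cytoplasm contrasts, the cell type contrasts and the differences, and 3 in each direction for the other 6 contrasts. Such genes needed a mean of at least 10.0 CPM in a compared group and all 3 libraries of one group above all 3 of the other. Symbols of predicted genes (Gm with a number, or ending in Rik) were passed over. The rule added the 2 members with the highest mean CPM of each list with at least 5 tested members, and each of the study genes. Some genes that the rule names are not reported here.

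The 23 lists hold 701 members, of which 673 were found in the count table, and 24 others were found in the TPM table alone. They cover nuclear lncRNAs, small nucleolar RNA host genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, SR proteins with CLK kinases and other genes with detained introns, ER chaperones and translocation, secreted and extracellular matrix proteins, immediate early transcripts, proliferation, neuronal splicing regulators, and synaptic receptors and ion channels. Marker lists cover pluripotency, neural progenitors, cortical neurons, inhibitory neurons, astrocytes, the oligodendrocyte lineage, microglia, endothelium, fibroblasts and mural cells, and primitive endoderm and mesoderm. The last list holds the study genes Gabbr1, Ptbp1, Ptbp2 and Meg3, chosen from what is known of the study, so their direction is not independent evidence. Lists with at least 5 tested members were tested with camera (limma 3.58.1), preset correlation 0.01, adjusted by Benjamini-Hochberg over 286 tests, and again with a correlation estimated from the data. Camera ranks a list against all other genes of the same contrast.

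The alternatives were RLE size factors, library totals alone, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the libraries compared, a block for the replicate number, no minimum fold change, no mitochondrial genes, and limma-trend on the deposited TPM values as log2(TPM + 1) and log2(TPM + 0.1), with at least 1 TPM in 3 libraries or no filter. DESeq2 changes size factors and test, the fit of only the libraries compared also the filter, and the TPM settings the table, scaling, test and genes. Each library was also left out in turn. Chosen after seeing the data were TPM values scaled by TMM, a fit without overlapping genes of which the other held over 0.1 of the count, and a fit without the 3 mESC libraries numbered 1. The replicate numbers were checked for pairing by correlating residuals of same-numbered libraries across genes. The correlations were 0.31 to 0.716 in mESC, -0.117 to 0.253 in mNPC and 0.027 to 0.137 in mCtx, so across genes same-numbered libraries shared variation in mESC and hardly in the others, although Xist and Eif2s3y ordered the mCtx replicates alike in each fraction. Replicates differed by more than counting error in each pair, with a chi-square per gene of 3.34 to 74.57.

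A self-test planted changes in 200 genes of counts simulated from the fitted means and spread of each gene. Of 100 genes planted at each size in mESC chromatin against cytoplasm, 91 were called at a log2 change of 1.5 and 100 at 3, with 14 of 17691 unchanged genes called. For the difference of mNPC and mESC, 74 and 91 of 100 were called, with 8 of 17654 unchanged genes. The list test found 1 of 1 planted list and called 0 of 20 unchanged lists. A fold against a group with no counts is given as a lower bound from 3 counts over the group, and a fold against 1 to 3 counts has its 95% interval from counting alone. Reads carry no molecular identifiers, so intervals and bounds cover counting error only. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not used here.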

Results

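Polyadenylated RNA was measured in the chromatin, nucleoplasm and cytoplasm of 3 mouse cell types along neuronal differentiation. The cell types were E14 embryonic stem cells kept with LIF (mESC), a neural progenitor line made in the submitters' laboratory and grown with EGF and FGF at 10.0 ng/ml (mNPC), and primary cortical neurons after 5 days in culture (mCtx). Each of the 9 groups has 3 biological replicates, so there are 27 libraries. RNA longer than 200 nt was taken from each fraction, and stranded libraries were read as pairs of 100 bp. Library totals ran from 13496984 to 20808290 counts in mESC, from 10622897 to 23608781 in mNPC and from 15607890 to 24537526 in mCtx.

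Mitochondrial transcripts were richest in the nucleoplasm fraction, whose purity was not tested. They made up 4.20% ± 0.317 of counts in mESC nucleoplasm against 0.614% ± 0.102 in chromatin and 0.037% ± 0.006 in cytoplasm (SD, n = 3). In mNPC the shares were 10.0% ± 1.52, 0.538% ± 0.205 and 0.385% ± 0.104, and in mCtx 6.58% ± 0.153, 1.44% ± 0.15 and 2.52% ± 0.112. Long noncoding RNAs were richest in chromatin, with 1.74% ± 0.13, 2.5% ± 0.107 and 2.23% ± 0.251 of counts in mESC, mNPC and mCtx, and 0.35% ± 0.053, 0.483% ± 0.006 and 0.643% ± 0.021 in cytoplasm. In each fraction the mESC library numbered 1 stood apart from the others.

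**Figure D1:**
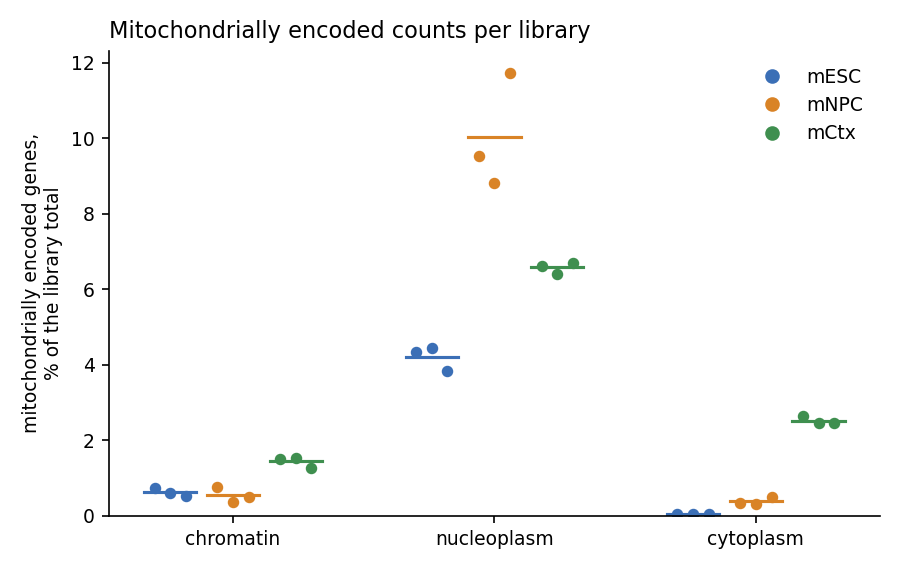
Share of counts from the mitochondrial genome (percent) in each of the 27 libraries by cell type and fraction, with a point per library and a line at the mean of 3. The nucleoplasm libraries lie above the chromatin and cytoplasm libraries of the same cell type, with means of 4.20%, 10.0% and 6.58%.

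Chromatin was compared with cytoplasm to ask which polyadenylated transcripts are relatively enriched in the chromatin fraction of each cell type. In mESC the loci of the stem cell microRNA cluster had some of the highest ratios. Mir294 (mm10 chromosome 7, 3220641 to 3220724, + strand) stood at 55.8 ± 8.26 CPM in chromatin and 0.243 ± 0.175 CPM in cytoplasm (SD, n = 3), with a log2 fold change 7.88 ± 0.56 (SE), adjusted p = 6.6e-09. Mir295 had 7.60 ± 0.59 and Mir291b 8.22 ± 0.59. Mir291a, with 3 or fewer counts over the cytoplasm, was 229-fold higher with a counting interval of 86.7 to 1230. Each locus is shorter than the RNA selected for sequencing. Malat1, a nuclear lncRNA of speckles (chromosome 19, 5795690 to 5802671, - strand), reached 1512 ± 299 CPM in chromatin against 19.98 ± 1.26 CPM in cytoplasm, a log2 fold change 6.24 ± 0.26 (SE), adjusted p = 1.8e-16. Gas5, a small nucleolar RNA host, rose by 4.44 ± 0.20 (adjusted p = 9.3e-16). The highest ratio belonged to Snord14d, which lies inside Hspa8, at 377-fold with a counting interval of 124 to 3710. Mir25 inside Mcm7 and Snord47 inside Gas5 had log2 fold changes of 8.07 and 7.45, and reads in these loci cannot be assigned to them alone. These ratios rest on few cytoplasmic counts. Without mESC cytoplasm 2 or 3 the log2 fold change of Snord14d was 11.37 or 7.97 and that of Mir291a 7.23 or 8.64. Mir291b had 9.06 without mESC cytoplasm 2, and Mir294 and Mir295 had 8.56 and 8.38 without mESC cytoplasm 1.

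On the cytoplasmic side of mESC, Rpsa, a ribosomal protein, stood at 363 ± 44.9 CPM in chromatin and 3825 ± 376 CPM in cytoplasm (SD, n = 3), a log2 fold change -3.40 ± 0.16 (SE), adjusted p = 1.6e-15. Dppa5a, a pluripotency marker, changed by -2.67 ± 0.15 on the log2 scale from 1393 ± 39.4 CPM in cytoplasm to 218 ± 20.3 CPM in chromatin. The lowest ratio was that of Gpx2, a glutathione peroxidase, at -3.84 ± 0.31, and Marcksl1, a membrane-cytoskeleton protein, had -3.64 ± 0.27. Rpsa-ps10 and Rps13-ps1 are pseudogenes that share reads with their parent genes, at -3.73 and -3.60.

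In mESC chromatin 16 of 18 nuclear lncRNAs (median 4.62) and 7 of 9 small nucleolar RNA hosts (median 2.42) were higher. Adjusted p was 7.7e-09 and 0.00133 in turn, and adjusted p = 0.0112 and 0.275 with an estimated correlation. Also higher were 25 of 40 SR protein and CLK kinase genes with 1 lower (median 1.47), 26 of 32 synaptic receptor and channel genes (median 2.76, or 2.80 at the bound) and 31 of 40 secreted and matrix genes (median 2.30, or 2.23 at the bound). Adjusted p was 2.0e-05, 1.3e-04 and 7.6e-07 in turn, and adjusted p = 0.510, 0.205 and 0.283 with an estimated correlation. Among them was Fn1, fibronectin, at 2.62 ± 0.21. The mitochondrial and ER lists were higher too, in 7 of 11 mitochondrial mRNAs (median 3.5, or 3.74 at the bound) and 15 of 36 ER chaperones with 4 lower (0.71). Adjusted p was 7.1e-04 and 0.0335 in turn, and adjusted p = 0.283 and 0.713 with an estimated correlation. Lower in mESC chromatin were 78 of 78 ribosomal protein genes (median -2.69), 65 of 74 respiratory chain genes (-1.80) and 27 of 35 proliferation genes with 3 higher (-1.83). Adjusted p was 1.4e-51, 3.6e-26 and 1.7e-09 in turn, and adjusted p = 0.0993, 0.180 and 0.325 with an estimated correlation. So were 22 of 39 pluripotency genes with 3 higher (median -1.33) and 30 of 44 immediate early genes with 4 higher (-1.35, or -1.37 at the bound). Adjusted p was 2.7e-04 and 5.7e-04 in turn, and adjusted p = 0.0789 and 0.126 with an estimated correlation. Counts adjusted over the list alone were the same.

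Of 18226 genes tested in mESC, 10198 were called, 6265 higher and 3933 lower in chromatin. With library totals as the scaling, which moved the median of all genes from 0.369 to 0.882, the split was 8098 higher and 2486 lower. In the deposited TPM values 84.3% of the calls were higher. Without the mESC libraries numbered 1 there were 10077 calls.

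In mNPC, Xist and Malat1 led the chromatin side. Xist, the lncRNA that coats the inactive X chromosome (chromosome X, 103460375 to 103483217, - strand), stood at 5886 ± 565 CPM in chromatin and 72.4 ± 11.1 CPM in cytoplasm (SD, n = 3), a log2 fold change 6.34 ± 0.73 (SE), adjusted p = 5.7e-08. Malat1 had 4247 ± 691 and 60.6 ± 2.22 CPM, a log2 fold change 6.13 ± 0.25 (SE), adjusted p = 7.8e-17. Gria2, an AMPA receptor subunit of neurons, was at 762 ± 59.3 CPM in chromatin and 18.3 ± 3.01 CPM in cytoplasm, a log2 fold change 5.38 ± 0.18 (SE), adjusted p = 2.2e-17. Srrm2, a speckle scaffold protein, rose by 3.73 ± 0.26. Mir5125 lies inside Srrm2, Ovgp1 overlaps Wdr77 and Tgfbr3l overlaps Map2k7, so their log2 fold changes of 6.05, 5.58 and 5.58 rest on shared reads. On the cytoplasmic side were Tmsb10, an actin-binding thymosin, at -5.35 ± 0.28, Eef1a1, a translation elongation factor, at -4.79 ± 0.18 with 15840 ± 1685 CPM in cytoplasm, and Vim, an intermediate filament protein of progenitors, at -3.11 ± 0.14. Tpt1-ps3, a pseudogene at -5.36, shares reads with its parent gene.

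In mNPC chromatin 78 of 78 ribosomal protein genes (median -4.26) were lower, with Rpl32 at -5.15 ± 0.19, and 15 of 18 nuclear lncRNAs with 1 lower (median 2.91) were higher. Adjusted p was 8.6e-95 and 2.1e-05 in turn, and adjusted p = 0.0259 and 0.0476 with an estimated correlation. Also higher were 33 of 40 SR protein and CLK kinase genes with 1 lower (median 2.36) and 18 of 32 synaptic receptor and channel genes (1.76, or 1.57 at the bound). Adjusted p was 8.0e-16 and 6.8e-04 in turn, and adjusted p = 0.189 and 0.245 with an estimated correlation. The lower lists further included 69 of 74 respiratory chain genes (median -2.51), 17 of 36 ER chaperones with 3 higher (-0.76) and 19 of 35 proliferation genes with 4 higher (-1.08). Adjusted p was 9.4e-36, 0.00134 and 1.0e-03 in turn, and adjusted p = 0.107, 0.594 and 0.635 with an estimated correlation. Against its list, Mki67, a marker of cycling cells, rose by 3.75 ± 0.20. Small nucleolar RNA hosts, mitochondrial mRNAs, secreted proteins, immediate early genes and neuronal splicing regulators did not pass, with adjusted p of 0.212, 0.862, 0.0514, 0.0665 and 0.858. Counts adjusted over the list alone were the same, apart from immediate early genes (17 lower over all genes, 16 alone).

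In mNPC 8904 genes were called, 5018 higher and 3886 lower in chromatin. The split was 6124 and 3087 with library totals, which moved the median of all genes from 0.116 to 0.432, and 82.8% of the calls in TPM values were higher.

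In mCtx, Xist, Col7a1 and Col11a2 led the named chromatin genes. Col7a1, a collagen of anchoring fibrils (chromosome 9, 108953586 to 108984875), stood at 22.4 ± 0.791 CPM in chromatin and 0.117 ± 0.0588 CPM in cytoplasm (SD, n = 3), a log2 fold change 7.42 ± 0.38 (SE), adjusted p = 6.3e-15, and Col11a2 had 6.63 ± 0.38. Xist stood at 2786 ± 2528 and 6.37 ± 5.67 CPM, a log2 fold change 8.73 ± 0.82 (SE), adjusted p = 2.1e-09, and was 7.71 without chromatin replicate 3 and 9.76 without cytoplasm replicate 3. The replicates differed alike in each fraction, and with a replicate block it was 8.75 ± 0.27. Amy1, an amylase whose span overlaps Rnpc3, had 5.73 ± 0.28. Gria2 rose by 2.85 ± 0.16, from 163 ± 20.6 to 1176 ± 56.5 CPM. The cytoplasmic side held Tmsb10 at -4.66 ± 0.27, Fth1, the ferritin heavy chain, at -4.59 ± 0.23, and Sst, the peptide of somatostatin interneurons (chromosome 16, 23889581 to 23890844), at -3.93 ± 0.18 with 294 ± 10.5 CPM in cytoplasm.

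Lower in mCtx chromatin were 78 of 78 ribosomal protein genes (median -3.31), 66 of 74 respiratory chain genes (-2.19) and 25 of 44 immediate early genes with 2 higher (-1.27). Adjusted p was 1.9e-61, 4.6e-24 and 0.00141 in turn, and adjusted p = 0.0717, 0.205 and 0.160 with an estimated correlation. Neuronal markers were lower as well, in 20 of 48 cortical neuron markers with 7 higher (median -0.77) and 9 of 16 inhibitory neuron markers with 1 higher (-1.11). Adjusted p was 0.00505 and 0.0123 in turn, and adjusted p = 0.205 and 0.174 with an estimated correlation. Among them Mapt, the tau protein, had -1.13 ± 0.23 and Tubb3, a neuronal tubulin, -1.45 ± 0.25, and with library totals Mapt was no longer called. Beside the neuronal markers, 11 of 15 microglia markers with 2 higher (median -2.08) and 15 of 36 ER chaperones with 2 higher (median -0.72) were lower. Adjusted p was 0.0349 and 4.0e-04 in turn, and adjusted p = 0.419 and 0.566 with an estimated correlation. Higher in chromatin were 11 of 18 nuclear lncRNAs with 3 lower (median 2.34, or 2.17 at the bound), 28 of 40 SR protein and CLK kinase genes (2.20) and 16 of 32 synaptic receptor and channel genes with 4 lower (1.05). Adjusted p was 0.00945, 2.0e-11 and 0.0176 in turn, and adjusted p = 0.223, 0.279 and 0.424 with an estimated correlation. The last list was 23 of 40 secreted and matrix genes with 8 lower (median 1.56). Adjusted p was 0.0296, and adjusted p = 0.674 with an estimated correlation. With a replicate block its adjusted p was 0.0766. Counts adjusted over the list alone were the same.

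In mCtx 9223 genes were called, 4780 higher and 4443 lower in chromatin. The split was 5653 and 3599 with library totals, which moved the median of all genes from 0 to 0.239, and 4360 and 4469 with at least 1 CPM in 3 libraries. In TPM values 81.3% of the calls were higher.

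The 3 chromatin-to-cytoplasm contrasts share no library, and 2341 genes were higher in chromatin in each of them, against 452.4 for independent lists, while 2034 were lower in each, against 204.4. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.698 between mESC and mNPC, 0.748 between mNPC and mCtx and 0.554 between mESC and mCtx (Spearman's rho 0.689, 0.755 and 0.535). Opposite calls were made for 204, 107 and 617 genes in these pairs. Among 1117 lncRNA genes, 645, 525 and 314 were higher and 44, 60 and 185 lower in chromatin of mESC, mNPC and mCtx, with medians of 2.13, 1.37 and 0.29.

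**Figure D2:**
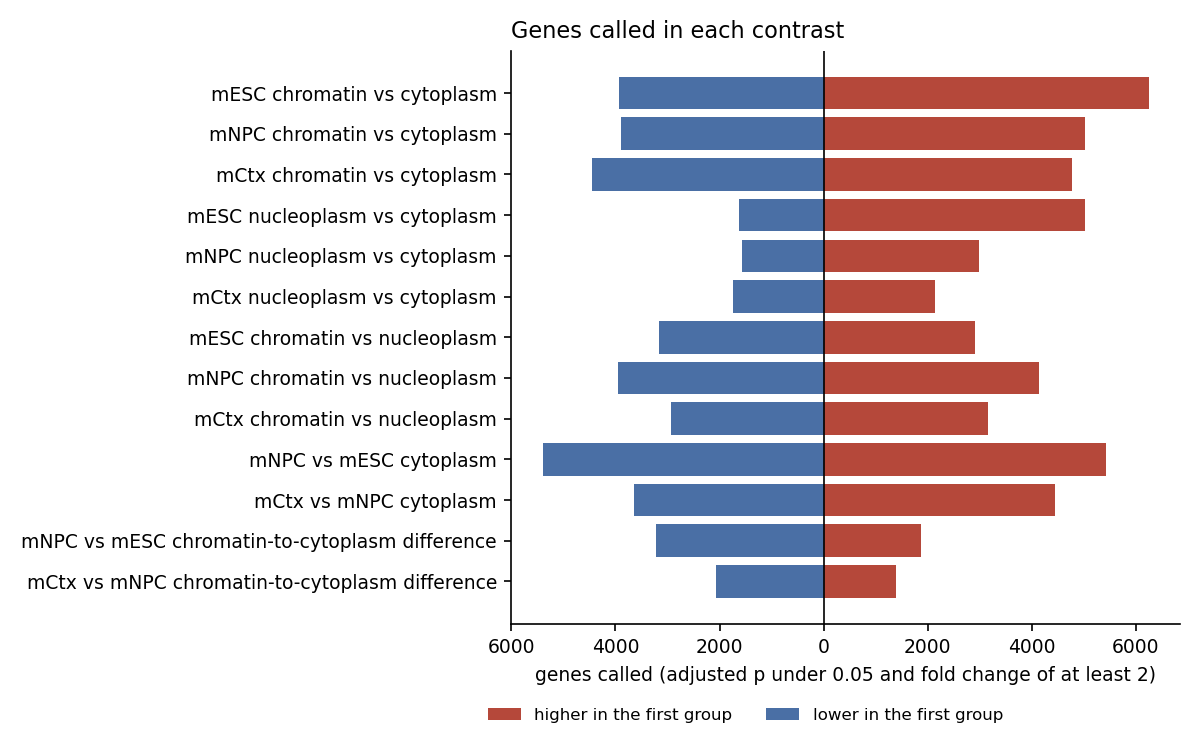
Number of genes called higher and lower in each of the 13 contrasts (edgeR quasi-likelihood, adjusted p under 0.05 and log2 fold change of at least 1, n = 3 per group). Chromatin against cytoplasm in mESC gave 6265 higher and 3933 lower genes.

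The study genes took different paths between the fractions. Gabbr1 (ENSMUSG00000024462, chromosome 17, 37045966 to 37075067, + strand), a subunit of the GABA-B receptor, was at 322 ± 42.5 CPM in chromatin and 15.2 ± 1.51 CPM in cytoplasm of mESC (SD, n = 3), a log2 fold change 4.40 ± 0.18 (SE), adjusted p = 1.9e-16. Its log2 fold change was 1.17 ± 0.16, adjusted p = 2.7e-07 in mNPC, and in mCtx it was -0.73 ± 0.16, adjusted p = 1.6e-04, under the minimum for a call. Ptbp1 (ENSMUSG00000006498, chromosome 10, 79854427 to 79864771, + strand), the splicing repressor of non-neuronal cells, had -2.08 ± 0.19, adjusted p = 3.1e-10 in mESC, -1.30 ± 0.19, adjusted p = 8.6e-07 in mNPC (-0.98 with library totals and 0.01 in log2(TPM + 1)) and 0.03 ± 0.19, adjusted p = 0.918 in mCtx. Ptbp2 (ENSMUSG00000028134, chromosome 3, 119718742 to 119783388, - strand), its neural paralog, had 2.14 ± 0.18, adjusted p = 7.6e-11 and 2.18 ± 0.18, adjusted p = 4.1e-11 in mESC and mNPC. In mCtx Ptbp2 had 0.99 ± 0.18, adjusted p = 1.5e-05, which was not called, though it was 1.04 with RLE size factors, 1.26 with library totals, and 1.02 without chromatin replicate 2 or cytoplasm replicate 1. Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726, + strand), an imprinted lncRNA, had 4.88 ± 0.35, adjusted p = 2.3e-12 in mESC and 4.28 ± 0.34, adjusted p = 1.4e-11 in mCtx, where chromatin held 8762 ± 105 CPM. In mNPC Meg3 was near the detection limit, with 154 counts over the chromatin and 4 over the cytoplasm, and a log2 fold change 5.08 ± 0.74 (SE), adjusted p = 9.2e-07.

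**Figure D3:**
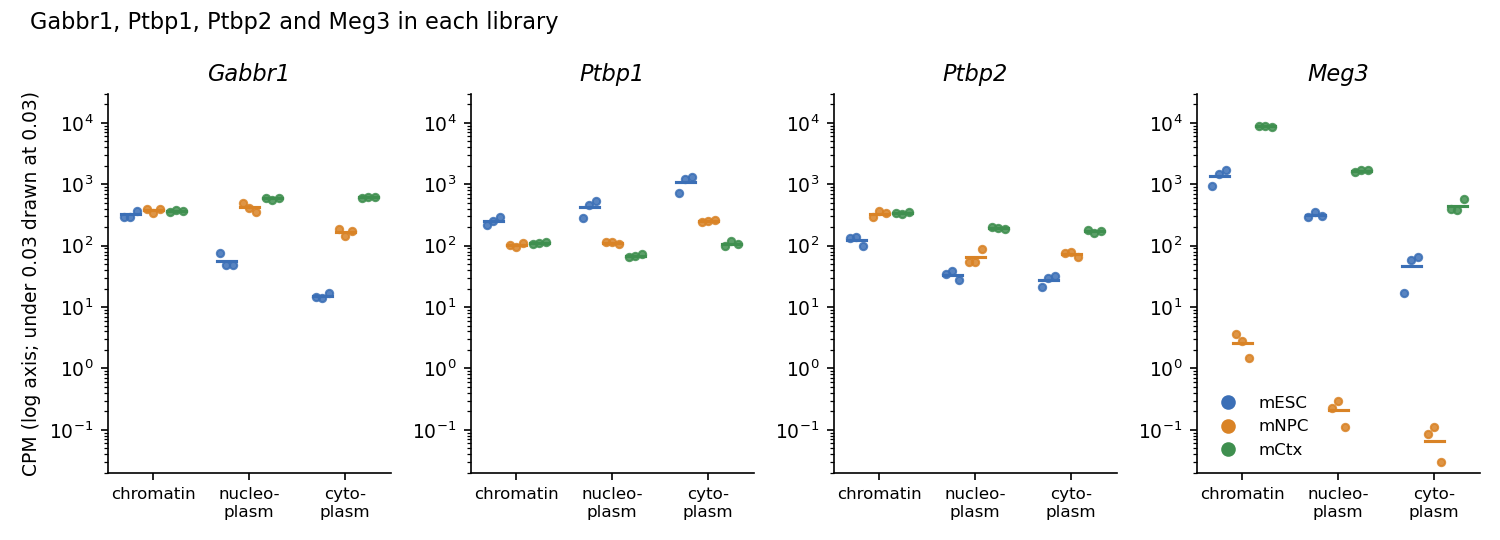
Level (CPM) of Gabbr1, Ptbp1, Ptbp2 and Meg3 in each library on a log axis, by cell type and fraction, with points for libraries, lines for means of 3, and values under 0.03 CPM drawn at 0.03. Gabbr1 in cytoplasm lies at 15.2, 168 and 613 CPM in mESC, mNPC and mCtx.

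Nucleoplasm was compared with cytoplasm to ask which transcripts are relatively enriched in the nucleoplasm fraction. Fraction purity was not tested, so a higher ratio does not by itself place a transcript in the nucleus. In mESC mitochondrial transcripts had some of the highest ratios to cytoplasm. The complex I subunit mt-Nd5 stood at 2335 ± 331 CPM in nucleoplasm and 13.1 ± 2.5 CPM in cytoplasm (SD, n = 3), a log2 fold change 7.48 ± 0.30 (SE), adjusted p = 8.0e-17. Canx, the ER chaperone calnexin, was at 2208 ± 59.0 and 204 ± 12.8 CPM, a log2 fold change 3.44 ± 0.13 (SE), adjusted p = 3.2e-17, and Fn1 had 3.74 ± 0.22. Neat1, the paraspeckle lncRNA, had 3.70 ± 0.37 (2.87 without nucleoplasm replicate 1), and Apoe, an apolipoprotein, 3.55 ± 0.46 (2.69 without nucleoplasm replicate 1 and 4.14 without cytoplasm replicate 1). Rpsa was lower at -1.43 ± 0.15, as were Tuba3a, a tubulin, at -1.70 ± 0.26 and Aldh1b1, a mitochondrial dehydrogenase, at -1.63 ± 0.28.

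Secretory lists were higher in mESC nucleoplasm, with 40 of 40 secreted and matrix genes (median 3.56, or 3.5 at the bound) and 30 of 36 ER chaperones (2.69), beside 10 of 11 mitochondrial mRNAs (median 6.86). Adjusted p was 4.1e-24, 1.5e-31 and 4.6e-14 in turn, and adjusted p = 0.0476, 0.0372 and 0.0262 with an estimated correlation. Nuclear RNAs were higher in 14 of 18 nuclear lncRNAs (median 2.45, or 2.86 at the bound) and 7 of 9 small nucleolar RNA hosts (median 1.70). Adjusted p was 2.9e-05 and 0.00213 in turn, and adjusted p = 0.0717 and 0.279 with an estimated correlation. Markers of other cell types were higher in 8 of 9 endothelial markers (median 2.87), led by the adhesion receptor Pecam1, and 6 of 14 primitive endoderm and mesoderm markers (median 0.57). Adjusted p was 0.0134 and 0.0419 in turn, and adjusted p = 0.160 and 0.283 with an estimated correlation. The second of these was lost with library totals (adjusted p = 0.0786). Higher too were 20 of 32 synaptic receptor and channel genes (median 1.94, or 1.90 at the bound), or 21 adjusted over the list alone. Adjusted p was 0.00652, and adjusted p = 0.379 with an estimated correlation. Lower in nucleoplasm were 14 of 78 ribosomal protein genes (median -0.66), 17 of 35 proliferation genes with 2 higher (-0.99) and 11 of 44 immediate early genes with 3 higher (-0.73, or -0.80 at the bound). Adjusted p was 1.5e-08, 4.0e-06 and 0.0193 in turn, and adjusted p = 0.592, 0.479 and 0.288 with an estimated correlation. The other counts were the same adjusted over the list alone. The calls numbered 6651, with 5021 higher and 1630 lower in nucleoplasm. The split was 4040 and 825 with only the libraries compared and 5538 and 562 with library totals, where the median of all genes moved from 0.04 to 0.26. The higher share was 57.5% in TPM values scaled by TMM, and 6281 genes were called without the mESC libraries numbered 1.

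In mNPC nucleoplasm, Ptprz1, Hsp90b1 and Ncan were higher beside mitochondrial mRNAs. Ptprz1, a receptor phosphatase of glial progenitors, was at 6520 ± 744 CPM in nucleoplasm and 301 ± 53.7 CPM in cytoplasm (SD, n = 3), a log2 fold change 4.44 ± 0.18 (SE), adjusted p = 4.2e-16. Hsp90b1, an ER chaperone, had 2044 ± 177 and 177 ± 11.2 CPM, a log2 fold change 3.53 ± 0.22 (SE), adjusted p = 3.3e-13, and Ncan, the proteoglycan neurocan, had 3.61 ± 0.25. The mitochondrial mt-Nd6 rose by 7.20 ± 0.39, while Rpl12 was lowest at -2.53 ± 0.18. Higher in mNPC nucleoplasm were 36 of 40 secreted and matrix genes (median 3.63, or 3.61 at the bound) (37 adjusted over the list alone), 11 of 11 mitochondrial mRNAs (median 5.26, or 5.19 at the bound) and 22 of 32 synaptic receptor and channel genes (median 2.03). Adjusted p was 6.2e-38, 5.2e-19 and 2.7e-09 in turn, and adjusted p = 0.00861, 0.0112 and 0.0476 with an estimated correlation. So were 21 of 36 ER chaperones (median 1.46), 8 of 14 oligodendrocyte lineage markers (1.54) and 8 of 15 astrocyte markers with 1 lower (1.27). Adjusted p was 7.8e-15, 0.00355 and 0.00481 in turn, and adjusted p = 0.150, 0.105 and 0.283 with an estimated correlation. Markers of other cell types lay as high without passing, with medians of 2.32 for fibroblast and mural genes and 3.22 at the bound for 7 of 14 primitive endoderm and mesoderm genes, or 0 for all (adjusted p = 0.148 and 0.0573). Neural progenitor markers were higher in 14 and lower in 4 of 37, where the median of -0.47 and the camera direction, upward, differ in sign. That call (adjusted p = 0.034) was lost with library totals (0.0565), a replicate block (0.342) and an estimated correlation (0.288). Lower in nucleoplasm were 67 of 78 ribosomal protein genes (median -1.45), 10 of 35 proliferation genes with 2 higher (-0.49) and 8 of 44 immediate early genes with 2 higher (-0.75). Adjusted p was 9.8e-36, 0.00505 and 0.0119 in turn, and adjusted p = 0.160, 0.689 and 0.275 with an estimated correlation. For immediate early genes the adjusted p was 0.0532 with library totals. The other counts were the same adjusted over the list alone.

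The mNPC calls numbered 4552, with 2992 higher and 1560 lower in nucleoplasm. This split moved with the setting: 3297 and 997 with RLE size factors, 3263 and 973 in DESeq2, 3271 and 945 with at least 1 CPM in 3 libraries, 3028 and 863 without overlapping genes, 2851 and 1030 with only the libraries compared, 3151 and 970 without mNPC nucleoplasm 2, 3267 and 835 without mNPC nucleoplasm 3, 2373 and 3248 with library totals, and 33.8% higher in TPM values. Library totals moved the median of all genes from -0.04 to -0.314.

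In mCtx nucleoplasm, Mki67 stood at 164 ± 2.02 CPM against 12.2 ± 2.5 CPM in cytoplasm (SD, n = 3), a log2 fold change 3.76 ± 0.20 (SE), adjusted p = 1.1e-12. Dync1h1, the dynein heavy chain, was at 2527 ± 130 and 233 ± 45.9 CPM, a log2 fold change 3.44 ± 0.26 (SE), adjusted p = 1.3e-10, and Amy1, which overlaps Rnpc3, had 3.5 ± 0.26. Lower in nucleoplasm were Pclaf, a PCNA-binding protein, at -2.46 ± 0.24, Rps12 at -2.44 ± 0.16 and Tmem98, a membrane protein, at -2.38 ± 0.29. Canx had 0.99 ± 0.12, adjusted p = 2.1e-07 and missed the minimum for a call, which it passed without cytoplasm replicate 1 (1.04) or 3 (1.01). Higher in mCtx nucleoplasm were 26 of 40 secreted and matrix genes with 1 lower (median 1.67) and 15 of 40 SR protein and CLK kinase genes (0.84). Adjusted p was 3.1e-12 and 3.6e-08 in turn, and adjusted p = 0.128 and 0.375 with an estimated correlation. So were 11 of 11 mitochondrial mRNAs (median 1.96) and 11 of 32 synaptic receptor and channel genes with 1 lower (0.77). Adjusted p was 1.6e-05 and 1.9e-04 in turn, and adjusted p = 0.176 and 0.205 with an estimated correlation. ER chaperones were higher in 6 and lower in 6 of 36 (median 0.10, adjusted p = 0.986). Lower were 70 of 78 ribosomal protein genes (median -1.40), 10 of 74 respiratory chain genes with 4 higher (-0.57) and 9 of 15 microglia markers (-1.49). Adjusted p was 4.5e-47, 0.00126 and 0.00122 in turn, and adjusted p = 0.105, 0.713 and 0.204 with an estimated correlation. Also lower were 11 of 44 immediate early genes (median -0.55), or 10 adjusted over the list alone, and 5 of 16 inhibitory neuron markers (median -0.31). Adjusted p was 0.00169 and 0.0489 in turn, and adjusted p = 0.164 and 0.262 with an estimated correlation. The second was lost with a replicate block (adjusted p = 0.0993). The other counts were the same adjusted over the list alone. The calls numbered 3878, with 2134 higher and 1744 lower. More were lower than higher with library totals (1870 higher, 2088 lower) and in TPM values scaled by TMM (1527 and 1690).

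Among the study genes, Gabbr1 had nucleoplasm-to-cytoplasm log2 fold changes of 1.90 ± 0.17, 1.31 ± 0.16 and -0.06 ± 0.16 in mESC, mNPC and mCtx, of which the first 2 were called. Ptbp1 had -1.35 ± 0.19, -1.16 ± 0.19 (-0.95 and no call without mNPC nucleoplasm replicate 3) and -0.66 ± 0.19. Meg3 had 2.75 ± 0.32, 1.47 ± 1.36 and 1.89 ± 0.30, of which that of mNPC was not called. Ptbp2 had 0.28 ± 0.18, -0.17 ± 0.18 and 0.19 ± 0.17, none of them called.

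Chromatin was compared with nucleoplasm to ask which transcripts are relatively enriched in chromatin over the nucleoplasm fraction. In mESC, Malat1 was at 1512 ± 299 CPM in chromatin and 237 ± 93.7 CPM in nucleoplasm (SD, n = 3), a log2 fold change 2.67 ± 0.22 (SE), adjusted p = 1.1e-10. Naaladl1, an aminopeptidase gene, had 3.47 ± 0.40 (4.33 without nucleoplasm replicate 1), and Mir25 inside Mcm7 and Mir5125 inside Srrm2 had 3.74 and 3.62. Canx changed by -2.21 ± 0.12 and mt-Nd5 by -3.71 ± 0.25. In mNPC, Xist was at 95.4 ± 28.0 CPM in nucleoplasm, a log2 fold change 5.95 ± 0.71 (SE), adjusted p = 1.4e-07, Malat1 had 3.87 ± 0.23, and Ncan -3.24 ± 0.25. The mitochondrial tRNA gene mt-Tw, which overlaps mt-Nd2, had -5.47 ± 0.34 (-6.12 without chromatin replicate 1). In mCtx, Xist had 6.78 ± 0.74 (5.75 without chromatin replicate 3 and 6.68 ± 0.24 with a replicate block) and Col7a1 3.90 ± 0.28, while mt-Nd6 had -3.25 ± 0.32. The fall of Cmss1, a ribosome biogenesis gene, in mCtx (-3.15 ± 0.64) rested on nucleoplasm replicate 3, without which it was -1.02.

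In mESC, 12 of 18 nuclear lncRNAs (median 1.65, or 1.79 at the bound) and 18 of 40 SR protein and CLK kinase genes (0.91) were higher in chromatin than in nucleoplasm. Adjusted p was 4.8e-06 and 1.5e-07 in turn, and adjusted p = 0.0266 and 0.403 with an estimated correlation. Lower were 31 of 36 ER chaperones (median -2.08), 24 of 40 secreted and matrix genes with 2 higher (-1.25) and 10 of 11 mitochondrial mRNAs (-3.45, or -3.43 at the bound). Adjusted p was 2.6e-28, 6.2e-07 and 7.3e-09 in turn, and adjusted p = 0.0445, 0.288 and 0.0717 with an estimated correlation. In mNPC, 13 of 18 nuclear lncRNAs with 1 lower (median 2.45, or 2.31 at the bound) and 36 of 40 SR protein and CLK kinase genes (2.13) were higher. Adjusted p was 1.4e-04 and 1.2e-19 in turn, and adjusted p = 0.0742 and 0.117 with an estimated correlation. Lower were 31 of 36 ER chaperones (median -2.47), 37 of 40 secreted and matrix genes (-2.61, or -2.63 at the bound) and 11 of 11 mitochondrial mRNAs (-5.17, or -5.11 at the bound). Adjusted p was 1.2e-22, 2.3e-15 and 2.0e-11 in turn, and adjusted p = 0.0717, 0.0993 and 0.0266 with an estimated correlation. In mCtx, 13 of 18 nuclear lncRNAs with 2 lower (median 1.90, or 1.78 at the bound) and 24 of 40 SR protein and CLK kinase genes (1.09) were higher. Adjusted p was 5.3e-04 and 4.6e-09 in turn, and adjusted p = 0.105 and 0.336 with an estimated correlation. Lower were 23 of 36 ER chaperones (median -1.22), 14 of 40 secreted and matrix genes with 2 higher (-0.57) and 11 of 11 mitochondrial mRNAs (-2.79). Adjusted p was 1.5e-08, 0.0468 and 5.0e-08 in turn, and adjusted p = 0.288, 0.695 and 0.0935 with an estimated correlation. Ribosomal protein genes were lower in 77, 78 and 74 of 78 genes of mESC, mNPC and mCtx (medians -2.12, -2.88 and -1.85). Their adjusted p was 1.1e-60, 1.1e-60 and 1.1e-49, and adjusted p = 0.0717, 0.0717 and 0.0993 with an estimated correlation. Respiratory chain genes were lower in 65, 69 and 63 of 74 (medians -1.91, -2.27 and -1.70). Their adjusted p was 1.0e-44, 7.1e-41 and 3.8e-37, and adjusted p = 0.0742, 0.0993 and 0.105 with an estimated correlation.

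Some marker lists were lower in chromatin than in nucleoplasm, in mESC 19 of 39 pluripotency genes with 2 higher (median -0.92), beside 15 of 35 proliferation genes (median -0.68) and 10 of 44 immediate early genes with 1 higher (-0.63, or -0.66 at the bound). Adjusted p was 6.5e-05, 2.6e-04 and 0.0179 in turn, and adjusted p = 0.0664, 0.594 and 0.283 with an estimated correlation. Higher in mESC chromatin were 9 of 23 neuronal splicing regulators (median 0.89) and 9 of 32 synaptic receptor and channel genes (0.82). Adjusted p was 0.00134 and 0.00652 in turn, and adjusted p = 0.0717 and 0.362 with an estimated correlation. In mNPC the markers were 17 of 37 neural progenitor markers with 2 higher (median -0.79), beside glial 8 of 15 astrocyte markers (median -1.27) and 9 of 14 oligodendrocyte lineage markers (median -2.02). Adjusted p was 0.00101, 7.2e-04 and 0.00357 in turn, and adjusted p = 0.137, 0.205 and 0.115 with an estimated correlation. In mCtx they were 23 of 48 cortical neuron markers with 1 higher (median -0.94) and 5 of 16 inhibitory neuron markers (-0.63), beside 11 of 44 immediate early genes with 2 higher (median -0.64). Adjusted p was 2.0e-08, 0.0352 and 0.0344 in turn, and adjusted p = 0.0243, 0.262 and 0.336 with an estimated correlation. Markers of other cell types lay as low without passing, with medians of -1.52 for endothelial and -1.18 for primitive endoderm and mesoderm genes in mESC (adjusted p = 0.212 and 0.107), of -2 for fibroblast and mural and -1.23 at the bound for 7 of 14 primitive endoderm and mesoderm genes, or 0 for all, in mNPC (adjusted p = 0.286 and 0.559) and of -1.10 for microglia and -1 for fibroblast and mural genes in mCtx (adjusted p = 0.542 and 0.218). For inhibitory markers the adjusted p was 0.0573 with library totals. These counts were the same adjusted over the list alone. Of the study genes, Ptbp2 had 1.86 ± 0.18, 2.35 ± 0.18 and 0.81 ± 0.17 in mESC, mNPC and mCtx, the last not called, and Gabbr1 2.5 ± 0.17, -0.15 ± 0.16 (1.81 in log2(TPM + 1)) and -0.67 ± 0.16, of which the first was called. Meg3 was called higher in each, at 2.13 ± 0.31, 3.61 ± 0.70 and 2.39 ± 0.31, and Ptbp1 in none, at -0.73 ± 0.19, -0.14 ± 0.19 (1.51 in log2(TPM + 1)) and 0.69 ± 0.19.

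The calls of chromatin against nucleoplasm numbered 6083 in mESC (2919 higher, 3164 lower), 8095 in mNPC (4135 and 3960) and 6095 in mCtx (3169 and 2926). With library totals the splits were 4387 and 2196, 6669 and 2446, and 4774 and 1719, as the median of all genes moved from 0.055 to 0.355, 0.053 to 0.646 and 0.041 to 0.392. In mNPC they were 3074 and 4691 with at least 1 CPM in 3 libraries and 2691 and 4393 without overlapping genes, and in TPM values 88.1%, 90.7% and 93.5% of calls were higher. RLE size factors moved the mESC median to 0.183, and 6426 genes were called in mESC without the libraries numbered 1.

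The cytoplasm of mNPC was compared with that of mESC for the first step of the neuronal series. Stem cell regulators were lost: Pou5f1, a core pluripotency factor (chromosome 17, 35506037 to 35510776), stood at 1252 ± 347 CPM in mESC (SD, n = 3) and had no counts in mNPC, at least 23400-fold lower. Dppa5a was at least 25500-fold lower, Zfp42 at least 14800-fold, L1td1 at least 10800-fold, Dnmt3l, a cofactor of DNA methylation, at least 6130-fold, and Sall4 at least 5460-fold. Tdh, the threonine dehydrogenase of stem cells, was 33500-fold lower with a counting interval of 8340 to 1840000. Glial progenitor genes rose: Olig1, a lineage factor, stood at 1779 ± 76.2 CPM against 1.15 ± 0.216, 1550-fold higher (adjusted p = 9.6e-23). Ptn, a growth factor, had 13.54 ± 0.40, and Vim 5.01 ± 0.16. Sparcl1, a matrix protein at 536 ± 119 CPM in mNPC, was at least 8630-fold higher. Fabp7, the fatty acid binding protein of radial glia, was 29100-fold higher (10800 to 153000) and Olig2 12900-fold (4890 to 69400). The fitted log2 fold changes without a library were 14.41 and 13.01 for Olig2 without mESC cytoplasm 2 and 3, and -14.41 and -16.87 for Tdh without mNPC cytoplasm 1 and 2.

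Lower in mNPC were 38 of 39 pluripotency genes (median -9.82, or -9.71 at the bound), and higher were 33 of 37 neural progenitor markers (median 6.27). Adjusted p was 2.3e-35 and 7.9e-32 in turn, and adjusted p = 5.1e-05 and 1.2e-04 with an estimated correlation. Without mNPC cytoplasm 1 or 3 the pluripotency median was -10.61 or -10.91. Glial markers were higher with the progenitor markers, in 15 of 15 astrocyte markers (median 7.47) and 11 of 14 oligodendrocyte lineage markers with 2 lower (5.03). Adjusted p was 6.9e-17 and 2.9e-06 in turn, and adjusted p = 0.00861 and 0.0347 with an estimated correlation. Also higher were 26 of 48 cortical neuron markers with 9 lower (median 1.46, or 1.51 at the bound), 23 of 40 secreted and matrix genes with 9 lower (2.19, or 2.28 at the bound) and 20 of 36 ER chaperones (1.34). Adjusted p was 0.00456, 4.9e-04 and 5.7e-04 in turn, and adjusted p = 0.205, 0.479 and 0.581 with an estimated correlation. So were 37 of 74 respiratory chain genes with 1 lower (median 0.99) and 6 of 11 mitochondrial mRNAs (3.05, or 3.48 at the bound). Adjusted p was 1.5e-04 and 0.0187 in turn, and adjusted p = 0.678 and 0.479 with an estimated correlation. Lower were 14 of 35 proliferation genes (median -0.64). Adjusted p was 0.00137, and adjusted p = 0.654 with an estimated correlation. Markers of other cell types did not pass. They were lower in 7 of 9 endothelial genes, in 10 of 14 primitive endoderm and mesoderm genes with 1 higher, in 5 of 12 fibroblast and mural genes with 3 higher and in 5 of 15 microglia genes with 1 higher (adjusted p = 0.0979, 0.0995, 0.854 and 0.420). Inhibitory neuron markers were higher in 8 and lower in 4 of 16 (adjusted p = 0.143). Counts adjusted over the list alone were the same.

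Calls numbered 10827 between mNPC and mESC cytoplasm, with 5438 higher and 5389 lower in mNPC. RLE size factors put the median of all genes at -0.156 and the split at 5057 and 5782. Of the study genes, Gabbr1 rose by 3.47 ± 0.18 and Ptbp2 by 1.39 ± 0.18, while Ptbp1 changed by -2.10 ± 0.19 and Meg3 by -9.19 ± 0.59 to 4 counts over the mNPC cytoplasm.

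The cytoplasm of mCtx was compared with that of mNPC for the second step of the series. Neurod2, a transcription factor of cortical projection neurons (chromosome 11, 98325415 to 98329648), stood at 302 ± 42.8 CPM in mCtx (SD, n = 3) and had no counts in mNPC, at least 5630-fold higher. Sst was at least 5400-fold higher at 294 ± 10.5 CPM, and Gabra5, a GABA receptor subunit, at least 2690-fold. Tubb3 (chromosome 8, 123411424 to 123422015) rose from 50.2 ± 11.8 to 2643 ± 284 CPM, a log2 fold change 5.72 ± 0.30 (SE), adjusted p = 3.9e-15, and Mapt from 85.9 ± 24.9 to 2654 ± 262 CPM, a log2 fold change 4.95 ± 0.27 (SE), adjusted p = 5.1e-15. Glial progenitor genes were lower, Olig1 by -3.30 ± 0.15 to 181 ± 17.3 CPM and Vim by -3.93 ± 0.15 to 196 ± 14.9 CPM. Actc1, a cardiac actin, was lowest at -11.21 ± 0.39, followed by Agt, the angiotensinogen of astrocytes, at -10.62 ± 0.47. Gpr17, a receptor of oligodendrocyte precursors, was 541-fold lower (191 to 5720). The fall of Fabp7 (-1.05 ± 0.17) was no call without mNPC cytoplasm 2 (-0.98) or 3 (-0.96) or mCtx cytoplasm 3 (-0.90).

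Higher in mCtx were 46 of 48 cortical neuron markers (median 5.05) and 30 of 32 synaptic receptor and channel genes (5.26). Adjusted p was 1.9e-45 and 1.3e-22 in turn, and adjusted p = 1.9e-06 and 0.00544 with an estimated correlation. So were 12 of 16 inhibitory neuron markers with 1 lower (median 4.81) and 17 of 23 neuronal splicing regulators with 4 lower (2.31, or 2.59 at the bound). Adjusted p was 6.7e-09 and 3.2e-09 in turn, and adjusted p = 0.00861 and 6.5e-04 with an estimated correlation. With these neuronal lists 13 of 15 microglia markers (median 5.79, or 5.75 at the bound) were higher. Adjusted p was 0.00101, and adjusted p = 0.239 with an estimated correlation. The microglia median was 7.12 without mNPC cytoplasm 3. Fibroblast and mural markers were higher in 8 and lower in 1 of 12 (median 4.09, or 3.96 at the bound, adjusted p = 0.190). Higher too were 10 of 11 mitochondrial mRNAs (median 3.28, or 3.14 at the bound). Adjusted p was 0.00195, and adjusted p = 0.325 with an estimated correlation. Lower were 23 of 37 neural progenitor markers with 3 higher (median -1.84), 14 of 15 astrocyte markers with 1 higher (-2.62) and 12 of 14 oligodendrocyte lineage markers (-3.81). Adjusted p was 1.6e-07, 2.3e-08 and 2.6e-07 in turn, and adjusted p = 0.0266, 0.0511 and 0.0243 with an estimated correlation. So were 30 of 35 proliferation genes (median -2.20), 7 of 78 ribosomal protein genes (-0.60) and 13 of 74 respiratory chain genes with 1 higher (-0.39). Adjusted p was 9.5e-16, 2.4e-04 and 0.00274 in turn, and adjusted p = 0.199, 0.713 and 0.738 with an estimated correlation. Endothelial markers were higher in 2 and lower in 1 of 9 (adjusted p = 0.938). Counts adjusted over the list alone were the same.

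Calls numbered 8093 between mCtx and mNPC cytoplasm, with 4448 higher and 3645 lower in mCtx. Gabbr1 rose by 1.87 ± 0.16, Ptbp2 by 1.22 ± 0.18 and Meg3 by 12.46 ± 0.58, while Ptbp1 changed by -1.21 ± 0.19.

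The chromatin-to-cytoplasm log2 fold change of mNPC minus that of mESC was tested. Fraction purity was not tested, and mitochondrial shares of cytoplasm were 0.037%, 0.385% and 2.52% in mESC, mNPC and mCtx. Gabbr1 had 4.40 in mESC and 1.17 in mNPC, a difference of -3.24 ± 0.23, adjusted p = 4.1e-11. Gas5 went from 4.44 to 0.51, a difference of -3.93 ± 0.25, adjusted p = 8.4e-12. Slc35f1, a member of a transporter family, went from 3.88 to -1.80, a difference of -5.68 ± 0.37, adjusted p = 1.1e-11. In the other direction, Srrm2 went from 1.71 to 3.73, a difference of 2.02 ± 0.33, adjusted p = 2.1e-05, and Dnd1, an RNA-binding protein of germ cells, from -2.36 to 2.57, a difference of 4.93 ± 0.43, adjusted p = 1.2e-09. Lin28a, a stem cell RNA-binding protein, had 5.60 ± 0.75, adjusted p = 1.1e-06 (6.45 without mNPC cytoplasm 3).

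Toward the cytoplasm moved 75 of 78 ribosomal protein genes (median -1.53), 33 of 36 ER chaperones (-1.40) and 7 of 11 mitochondrial mRNAs (-3.34, or -3.41 without genes at 0). Adjusted p was 1.2e-33, 1.4e-17 and 3.0e-07 in turn, and adjusted p = 0.178, 0.115 and 0.0993 with an estimated correlation. So did 20 of 40 secreted and matrix genes (median -1.28, or -1.24 without genes at 0) (21 adjusted over the list alone), 21 of 74 respiratory chain genes (median -0.50) and 5 of 9 small nucleolar RNA hosts with 1 higher (median -1.67). Adjusted p was 2.4e-05, 0.00130 and 0.00903 in turn, and adjusted p = 0.373, 0.713 and 0.340 with an estimated correlation. Lower as well were 5 of 18 nuclear lncRNAs (median -1.02, or -0.84 without genes at 0) and 8 of 23 neuronal splicing regulators with 1 higher (-0.89, or -0.88 without genes at 0). Adjusted p was 0.0480 and 0.0424 in turn, and adjusted p = 0.338 and 0.25 with an estimated correlation. These were lost with library totals (adjusted p = 0.127 and 0.0648), and the lncRNAs with a replicate block (0.0673). Toward chromatin moved 20 of 40 SR protein and CLK kinase genes (median 0.98) (20 higher and 1 lower adjusted over the list alone), 9 of 35 proliferation genes with 1 lower (median 0.61) and 9 of 44 immediate early genes with 3 lower (median 0.53, or 0.54 without genes at 0). Adjusted p was 2.5e-09, 1.9e-04 and 0.0463 in turn, and adjusted p = 0.325, 0.592 and 0.365 with an estimated correlation. The other counts were the same adjusted over the list alone. The calls numbered 5104, with 1878 higher and 3226 lower. With library totals they were 1298 and 3929, as the median of all genes moved from -0.192 to -0.4, and without the mESC libraries numbered 1 there were 5306 calls.

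In the same test of mCtx minus mNPC, Gria2 went from 5.38 in mNPC to 2.85 in mCtx, a difference of -2.53 ± 0.22, adjusted p = 9.0e-09. Malat1 went from 6.13 to 2.17, a difference of -3.97 ± 0.30, adjusted p = 4.3e-10, with 791 ± 49.5 CPM in mCtx chromatin. Mllt11, a gene of differentiating neurons, stood at 134 ± 2.96 CPM in chromatin and 1165 ± 43.8 CPM in cytoplasm of mCtx (SD, n = 3), and its difference was -4.16 ± 0.29, adjusted p = 1.3e-10. Gabbr1 had -1.90 ± 0.22, adjusted p = 3.5e-07, Ptbp2 -1.19 ± 0.25, adjusted p = 5.3e-04, and Ptbp1 1.33 ± 0.26, adjusted p = 3.4e-04. Higher in mCtx were also Orai3, a calcium channel, at 3.89 ± 0.30, adjusted p = 5.4e-10, and Pygm, the muscle glycogen phosphorylase, at 4.42 ± 0.42, adjusted p = 1.9e-08. Khdrbs2, a neuronal splicing regulator, had 4.78 ± 0.53, adjusted p = 1.8e-07 in counts and -0.78 in log2(TPM + 1).

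Neuronal lists moved toward the cytoplasm in 14 of 48 cortical neuron markers with 2 higher (median -0.72), 11 of 32 synaptic receptor and channel genes (median -0.82, or -0.46 without genes at 0) (12 adjusted over the list alone) and 6 of 16 inhibitory neuron markers with 1 higher (median -1.57, or -1.33 without genes at 0). Adjusted p was 2.9e-04, 0.0172 and 0.00722 in turn, and adjusted p = 0.0993, 0.441 and 0.138 with an estimated correlation. Microglia and endothelial markers moved as far without passing, with medians of -2.61 (-2.33 over the 7 with counts in each group) and -1.18 (-1.01 over 5), adjusted p = 0.123 and 0.864. Lower too were 5 of 18 nuclear lncRNAs with 1 higher (median -0.75, or -0.80 without genes at 0) (6 lower and 2 higher adjusted over the list alone), 6 of 40 SR protein and CLK kinase genes with 1 higher (median -0.59) and 9 of 44 immediate early genes with 1 higher (median -0.54). Adjusted p was 0.0126, 0.00583 and 0.0243 in turn, and adjusted p = 0.223, 0.689 and 0.300 with an estimated correlation. For the lncRNAs the adjusted p was 0.0922 with a replicate block. Also lower were 5 of 11 mitochondrial mRNAs (median -1.28, or -1.09 without genes at 0). Adjusted p was 0.0164, and adjusted p = 0.479 with an estimated correlation. Toward chromatin moved 41 of 78 ribosomal protein genes (median 1.03), 13 of 74 respiratory chain genes with 1 lower (0.43) and 8 of 35 proliferation genes (0.47). Adjusted p was 4.6e-26, 2.9e-06 and 5.1e-04 in turn, and adjusted p = 0.249, 0.609 and 0.610 with an estimated correlation. The other counts were the same adjusted over the list alone. The calls numbered 3472, with 1400 higher and 2072 lower.

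**Figure D4:**
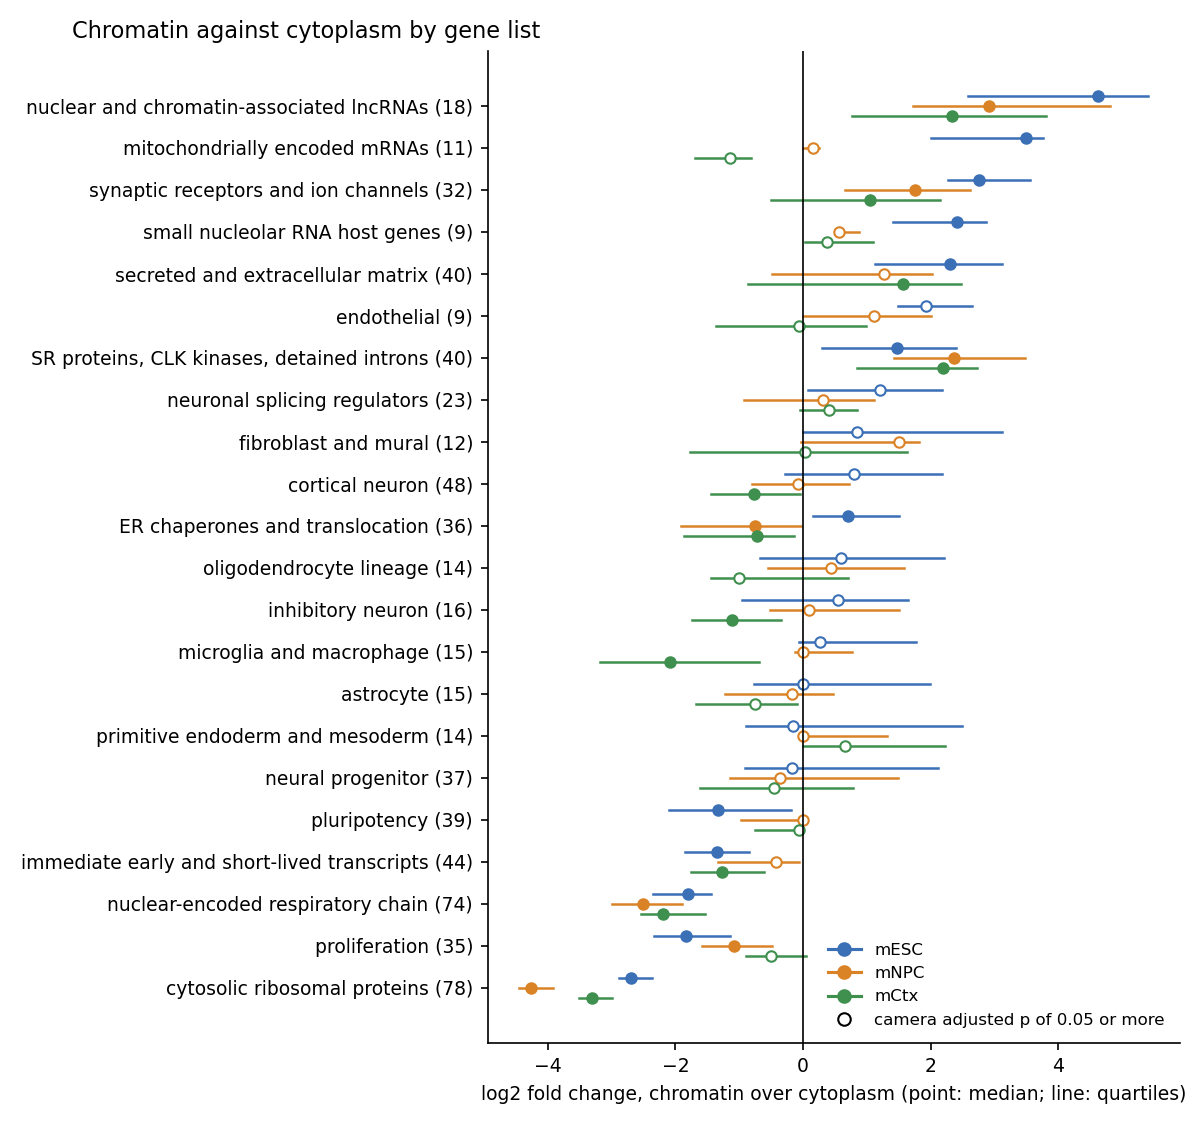
Median log2 fold change of each gene list in chromatin against cytoplasm of each cell type. Points are medians, lines quartiles of tested genes, and open points mark a camera adjusted p of 0.05 or more. Ribosomal protein genes lie at -2.69, -4.26 and -3.31 in mESC, mNPC and mCtx.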

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

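No test of this part was chosen after its result was seen. Each result is either a difference between cell types in the chromatin-to-cytoplasm log2 fold change, tested itself in edgeR, or a signal of a listed gene that the count table does not hold.

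Between mNPC and mESC, 5104 genes differed in their chromatin-to-cytoplasm log2 fold change. The largest differences toward mNPC chromatin were those of Ifitm1 (7.5), Eras (6.42), Sox15 (5.65), Lin28a (5.6), Isyna1 (5.49), Bhlha15 (5.43), Dnd1 (4.93) and Syne4 (4.77). Toward mNPC cytoplasm they were those of Chrdl1 (-7.06), Kcnk6 (-6.81), Igsf1 (-6.74), Nkain3 (-6.73), Slc35f1 (-5.68), Serpinf1 (-5.62), Zfp978 (-5.5) and Gsg1l (-5.38), and Gabbr1 had -3.24. Eras, Bhlha15, Chrdl1, Kcnk6, Igsf1, Nkain3, Serpinf1 and Gsg1l have 3 counts or fewer in a group, so their values depend on the prior count and are no bounds. Eras was no call without mESC chromatin 1 (adjusted p = 0.0502), without any 1 mNPC chromatin library (0.077 to 0.0871) or without any 1 mNPC cytoplasm library (0.0586 to 0.0726). Bhlha15 was no call without mNPC chromatin 1 (0.0677) or 2 (0.191) or any 1 mNPC cytoplasm library (0.0573 to 0.0753). Ifitm1 had 6.88 without mESC cytoplasm 2 and 9.33 without mNPC cytoplasm 1, Sox15 7.48 without mNPC cytoplasm 1, Lin28a 6.45 without mNPC cytoplasm 3 and Serpinf1 -7.42 without mNPC chromatin 2.

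Between mCtx and mNPC, 3472 genes differed. Toward mCtx chromatin the largest were Kcnb2 (4.88), Khdrbs2 (4.78), Prkg1 (4.69), Calb2 (4.68), Pygm (4.42), Tfr2 (4.25), Orai3 (3.89) and Nwd2 (3.46). Toward mCtx cytoplasm they were Dlx6os1 (-6.19), Dlx1as (-4.49), Mllt11 (-4.16), Mdk (-4.02), Kcna2 (-4.01), Malat1 (-3.97), Gpr21 inside Rabgap1 (-3.97) and Gpr26 (-3.96). Of the study genes, Ptbp1 had 1.33, Ptbp2 -1.19 and Gabbr1 -1.9. Kcnb2, Calb2, Nwd2, Gpr26 and Dlx6os1 have 3 counts or fewer in a group of mNPC, so their values are no bounds. In log2(TPM + 1) the sign was opposite for Kcnb2 (-0.05), Khdrbs2 (-0.78), Calb2 (-0.07), Gpr26 (0.35) and, without a filter, Prkg1 (-0.32). Kcnb2 was no call without any 1 mNPC chromatin library (adjusted p = 0.0566 to 0.0703) or mNPC cytoplasm 2 (2.25, adjusted p = 1), and had 5.55 without mNPC cytoplasm 1. Nwd2 had 5.28 without mNPC chromatin 1 and was no call without mNPC chromatin 2 (0.066) or mNPC cytoplasm 2 (0.0638) or 3 (0.0723). Gpr26 was no call without mNPC chromatin 2 (0.0927) or any 1 mNPC cytoplasm library (0.056 to 0.091), nor in DESeq2 (0.0557). Dlx1as had -3.77 and -7.65 without mNPC cytoplasm 1 and 3.

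The gene lists that differed between mNPC and mESC had median differences of -3.34 for mitochondrial mRNAs, -1.67 for small nucleolar RNA hosts, -1.53 for ribosomal proteins, -1.4 for ER chaperones, -1.28 for secreted proteins, -1.02 for nuclear lncRNAs, -0.89 for splicing regulators, -0.5 for the respiratory chain, 0.53 for immediate early genes, 0.61 for proliferation and 0.98 for SR proteins and CLK kinases. Between mCtx and mNPC they were -1.57 for inhibitory neurons, -1.28 for mitochondrial mRNAs, -0.82 for synaptic receptors (-0.46 without genes that have no counts in a group), -0.75 for nuclear lncRNAs, -0.72 for cortical neurons, -0.59 for SR proteins and CLK kinases, -0.54 for immediate early genes, 0.43 for the respiratory chain, 0.47 for proliferation and 1.03 for ribosomal proteins. None of these 21 passed the camera test with an estimated correlation, where the lowest adjusted p was 0.0993.

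The 10 splits of a difference's 6 chromatin and cytoplasm pairs are too few for a share under 0.05. The real splits gave 5104 and 3472 calls and the highest of the others 0 and 0.

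The 77 cortical neuron and synaptic receptor genes had a median difference of -0.73 between mCtx and mNPC, and microglia (-2.61) and endothelial markers (-1.18) moved as far. Gene length is argued against, since -0.73 lay at percentile 0 of 10000 random lists matched on mean expression and gene span, whose median was -0.02. Whether any gene higher in cytoplasm of mCtx by as much shows the same is open: lists matched on expression and the cytoplasmic change had a median of -0.63 and the genes lay at percentile 25.58 of them, but that change is part of the difference, so this decides nothing. Whole-span counting is open too, since in log2(TPM + 1) the median lay at -0.28 from that of all genes, between the bounds set before the test. A difference in retention or export between the cell types was not tested and remains a hypothesis.

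Of the listed genes, 24 are in the TPM table alone and in no count-based comparison. There were no control samples, and the values given are mean TPM in the group with the highest mean (n = 3). In mCtx chromatin they were 3060 for Rian, 867 for Miat, 514 for Snhg14, 285 for Mirg, 259 for Mir124a-1hg, 37.3 for A330023F24Rik, 7.38 for Rmst and 2.8 for Kcnq1ot1. In mESC chromatin Snhg1 had 1030, Gm26917 997, Snhg5 430, 5430416N02Rik 146, Pvt1 53.6 and Dancr 9.17. In mNPC chromatin Mir9-3hg had 296, Dleu2 129, 1810026B05Rik 118, Sox2ot 38.1 and Jpx 29.8. In mNPC cytoplasm Rpl24 had 1780, Snhg8 273 and Snhg6 244, while Peg13 had 136 in mCtx nucleoplasm and Snhg18 2.22 in mCtx cytoplasm.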

How the results depend on the processing

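Chosen after the results were seen were TPM values scaled by TMM, the fit without overlapping genes and the fit without the 3 mESC libraries numbered 1. The 13 counts of called genes and the count shared by the chromatin-to-cytoplasm contrasts stayed within 1.5 times their value with RLE size factors, library totals, no filter, at least 1 CPM in 3 libraries, DESeq2, a fit of only the libraries compared, a replicate block, no mitochondrial genes, TPM values scaled by TMM and no overlapping genes, as did the 6 counts of mESC without its libraries numbered 1. No gene also called in an edgeR or DESeq2 setting changed sign. Leaving out 1 library gave 9946 to 10531, 8740 to 8931 and 9039 to 9190 calls for chromatin against cytoplasm of mESC, mNPC and mCtx. Some alternatives, or leaving out 1 library, turned which direction held more calls for chromatin against nucleoplasm of each cell type, chromatin against cytoplasm of mCtx, nucleoplasm against cytoplasm of mNPC and mCtx, and mNPC against mESC cytoplasm. The self-test, with few changed genes, called 91 and 74 of 100 planted at a log2 of 1.5.

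With no minimum fold change, which admits more genes by construction, the calls numbered 11521, 8967 and 8523 for nucleoplasm against cytoplasm of mESC, mNPC and mCtx, 10482 and 10526 for chromatin against nucleoplasm of mESC and mCtx, 5830 for the difference of mCtx and mNPC, and 3623 genes were shared. In log2(TPM + 1), chromatin against nucleoplasm gave 9207 in mESC and 12182 in mNPC, the difference of mCtx and mNPC 5417, and the shared count was 4950. Without a filter these were 9274, 12209, 5357 and 4920. In log2(TPM + 0.1), chromatin against nucleoplasm gave 11590, 14817 and 11442 in mESC, mNPC and mCtx, chromatin against cytoplasm of mNPC 14714, the difference 5592 and the shared count 7494. Scaling log2(TPM + 1) values by TMM brought each of these 14 counts within 1.5 times of the count-based one, so the rise in log2(TPM + 1) goes with the missing scaling between libraries. For log2(TPM + 0.1) the cause was not tested.

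In TPM values 13 results had the opposite sign. In log2(TPM + 1), with or without the filter, Calr, Ptbp1 and Atp5b had 0.28, 0.01 and 0.2 for chromatin against cytoplasm, the first 2 in mNPC and the third in mCtx, and Ptbp1 and Gabbr1 had 1.51 and 1.81 for chromatin against nucleoplasm of mNPC. With TPM + 0.1 the values were 0.28, 0.01, 0.2, 1.53 and 1.82. In the difference of mNPC and mESC, Meg3 had -3.62, or -3.24 scaled by TMM. In that of mCtx and mNPC it had 3.81, or 3.4 scaled. Kcnb2 had -0.05, Khdrbs2 -0.78, Calb2 -0.07 and Gpr26 0.35. With TPM + 0.1 Kcnb2, Khdrbs2 and Gpr26 had -0.35, -1.63 and 0.02, and scaled by TMM Kcnb2, Khdrbs2 and Calb2 had -0.68, -1.1 and -0.88. Without a filter Prkg1 had -0.32 and, for chromatin against cytoplasm of mESC, Snord47 -0.7. The cause was not tested.

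Of 313 values of named genes, 311 kept their direction and side of the threshold with RLE size factors, 302 with library totals (8 no longer past it, 3 newly past it), 312 with no filter, 312 with at least 1 CPM, 310 in DESeq2 (1 and 2), 302 with no minimum fold change (11 newly past it) and 313 with a replicate block. It was 311 of 312 with only the libraries compared, 289 of 289 without mitochondrial genes, 284 of 285 without overlapping genes, 127 of 127 without the mESC libraries numbered 1, and 2160 of 2196 with 1 library left out, where 29 lost and 7 gained a call. In TPM values 263 of 302 were kept in log2(TPM + 1), 264 in log2(TPM + 0.1), 263 of 305 without the filter and 283 of 302 scaled by TMM.

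The list tests depended on the correlation between genes. Of 135 past the threshold, 23 passed with it estimated, 129 with library totals and 130 with a replicate block. Without 1 library camera was not rerun, and 936 of 936 medians kept their sign. Among 100 drawn regroupings of the libraries, the real one included, 1 gave as many list tests as 135. The others gave 104 to 132 (median 119), but mixed groups keep part of the real difference, so this decides nothing. Of 100 drawn regroupings only the real one gave 2341 shared genes and the others 0. This follows from the 0 calls of other splits in mNPC and mCtx and shows nothing further.

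For a single contrast the 10 splits of 6 libraries are too few for a share under 0.05. Other splits mix the groups compared, which adds spread, so their low counts decide nothing. The highest other was 751, 0 and 0 calls for chromatin against cytoplasm of mESC, mNPC and mCtx. For nucleoplasm against cytoplasm it was 1523, 0 and 0, for chromatin against nucleoplasm 1402, 0 and 0, and for cell types 1 and 1. In mESC, where same-numbered libraries vary together, the highest other among the 4 splits that part each pair was 0 in each contrast.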

Other observations

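Chosen after their results were seen were the gene families below, the test of nascent RNA over introns, and the tests of female and male cell shares and of swapped labels. Of 17 cytosolic aminoacyl-tRNA synthetases, 9 were lower in nucleoplasm than in cytoplasm of mESC (median log2 fold change -1.05) and none higher, none of them passed in mNPC (median -0.21), and 10 were higher in mCtx nucleoplasm (median 1.16) and none lower. The nucleoplasm-to-cytoplasm difference of mCtx and mESC was tested itself, and 17 of 17 were higher (median 2.1, or 1.8 with library totals). Among them Aars and Lars had 3.12 ± 0.24 and 3.07 ± 0.29 (SE, n = 3). Of 7 subunits of the cytosolic chaperonin, 6 were lower in mESC nucleoplasm (median -1.16) and 1, Cct6b, was higher (1.48), while 2 were higher in mCtx (median 0.9). In the difference 6 of 7 were higher (median 1.75), with Cct8 at 2.18 ± 0.26. These directions held with RLE size factors and library totals.

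Of 78 potassium channel genes, 45 were higher in mESC nucleoplasm than in cytoplasm (median 1.66) and 33 in mNPC with 2 lower (1.22). In mCtx 6 were higher and 7 lower (0.01, and -0.07 with library totals). In the difference from mESC 36 were lower and 0 higher (median -1.67). Tubulins (1.26), kinesins (0.98), ABC transporters (-1.39) and protocadherins (-1.54) shifted too, zinc finger proteins hardly (0.01). Proteasome subunits were lower in chromatin than in cytoplasm in 43, 38 and 29 of 48 genes of mESC, mNPC and mCtx (medians -2.03, -1.71 and -1.15). The 1561 shortest protein-coding genes (up to 4.2 kb) had median chromatin-to-cytoplasm log2 fold changes of -1.01, -0.86 and -1.29. The 1561 longest (132.48 kb or more) had 1.2, 0.46 and 0.53. Counts include introns and camera tests were not span-matched.

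The mRNAs of ER chaperones and secreted proteins were higher in nucleoplasm than in cytoplasm of mESC and mNPC. Nascent RNA counted over introns is argued against, since chromatin lay below nucleoplasm for both lists in both cell types, the highest of the 4 medians being -1.25. Whole-span counting is argued against as well, since in log2(TPM + 1) the lists lay 1.12 to 2.63 above the median of all genes. ER membrane carried into the nucleoplasm fraction may account for the pattern, since 409 other genes of the Slc, Tmem and Itg families had medians of 2.1 and 1.07 in mESC and mNPC against -0.9 and -0.67 for 116 genes of cytosolic families, and the smaller of these gaps was 1.74. A difference between cell types in nuclear retention was not tested and stays open.

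Xist and Y-linked genes occurred together in mNPC and in mCtx, and differed between mCtx replicates, with Xist at 765.9, 1971 and 5621 CPM and Eif2s3y at 108.7, 74.81 and 17.38 CPM in chromatin of mCtx replicates 1, 2 and 3. Library labels swapped within a fraction are argued against, since the order of the replicates was the same in 3 of 3 fractions. Cultures with different shares of female and male cells may account for mCtx, since the replicate with the most Xist had the least of 4 Y-linked genes in 12 of 12 comparisons, which is a hypothesis found on the same data. In mNPC chromatin, with Xist at 5235, 6242 and 6181 CPM and Eif2s3y at 109, 94.35 and 99.63 CPM, silencing by Xist of the single X chromosome of a male line is argued against, since 460 X-linked genes had a median change from mESC 0.48 above that of 12538 autosomal genes (95% bootstrap interval 0.16 to 0.74). The source of the line and of the cultures was not tested and stays open.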
